A study of Mus musculus with 6 samples.

How the data were processed

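Small RNA was sequenced from mouse hearts of the C57BL/6J strain, an inbred laboratory strain. Per the labels, the series holds 6 samples in 2 groups of 3 biological replicates, taken at 12 weeks of age. One group was the border zone of an infarct 2 weeks after surgery and the other was the matching region after sham surgery, in which no infarct is made. Per the labels' protocols, small RNA libraries were made with an Illumina kit from total RNA extracted with Trizol and sequenced on a Genome Analyzer IIx. The submitters' processing notes name DESeq, with no role or version. The aligner, the genome build, the miRBase release and any filter on which miRNAs were kept are not given in the sources used here.

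The authors deposited a single table for the whole series, with a column of miRNA names and 6 columns of values. The headers of these 6 columns are short codes that occur in no label of any sample, in no title, description, source name or characteristic, and not in the design text. No column could therefore be matched to a sample or to a group by name. Column order and the values themselves were not accepted as evidence of which column is which, because no source states the order of the columns, and assigning groups from the values would assume the result that the comparison is meant to test. The value columns were looked at once, when the file was first described. All 6 were then left out of every step reported here, and no level, fold change, depth or test is given.

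The names in the table were the only data analysed. They were read with Python 3.11.15 and pandas 2.3.3. Each name was matched to the mouse miRNA genes of an NCBI gene table for assembly GRCm38.p6, first by gene symbol and otherwise by a synonym, after removal of the species prefix, the asterisk and the arm suffix. A name without a copy number was matched to all numbered copies of its gene. Where a synonym led to a gene whose symbol only adds the letter a, as Mir193a for miR-193, only that gene was kept. The genome build behind the deposited table is not known, so no coordinates are printed, and the assembly served only for gene names and for which genes lie next to each other. Genes were called neighbours when at most 10 kb separated them, and a cluster had to hold genes of at least 2 differently named miRNAs.

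The names were also compared with 16 lists of miRNAs that had been fixed before the data were examined, from general knowledge of heart tissue, its cell types and injury. The lists were 6 cardiomyocyte miRNAs, 9 fibroblast, 8 antifibrotic (the miR-29 and miR-30 families), 6 of the miR-15 family, 9 of the let-7 family, 12 of the miR-17 cluster and its paralogues, 4 endothelial, 3 smooth muscle, 8 leukocyte, 4 erythroid, 8 stress-induced, 4 of the miR-26 and miR-101 families, 6 of an X-linked cluster, 40 of the imprinted Dlk1-Dio3 region, 10 epithelial, and 7 markers of liver, neurons or skeletal muscle. A list member counted as listed when the table held its current miRBase name, that name without the arm, or an older name of the same arm. miR-21, miR-208b and miR-322 each stand on 2 lists and were counted once in totals over lists.

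The planned tests between sham and infarcted hearts were limma on log2 values, camera on the lists, and a permutation test of the share of cardiomyocyte miRNAs. None was run, and the planned rule for naming individual miRNAs, which ranks them by fold change and p-value, was not used. The miRNAs named in the text were chosen by their list or cluster. A listed name shows only that the authors' table has a row for that miRNA, and does not give its abundance in either group.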

Results

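The study asked how the small RNA content of the mouse heart differs between the border zone of an infarct and sham-operated tissue, 2 weeks after surgery, with 3 biological replicates in each of the 2 groups. The deposited table listed 440 mature miRNAs, each once, with 6 columns of values whose headers match no sample label. Sham and infarcted hearts could therefore not be told apart in the table, and the comparison that the design implies was not made. No miRNA is reported here as higher or lower after infarction, and library depth was not analysed here. What follows describes which miRNAs the table covers, by name.

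Of the 440 names, 234 carried neither an arm nor an asterisk, 101 named the 5p or 3p arm without an asterisk, and 105 carried the asterisk that older miRBase releases gave to the less abundant strand of a precursor. For 120 names, taken without arm and asterisk, the table listed 2 entries, one for each strand. These included miR-21 and miR-21*, from the precursor of the fibroblast and injury miRNA miR-21, and miR-208a-3p with miR-208a-5p, from an intron of the cardiac myosin gene Myh6. A further name, miR-3102, had more than 2 entries. Names with a copy number were counted apart. Strands listed as miR-24 with miR-24-1* and miR-24-2*, for example, are not among the 120, so more precursors had both strands listed. Strand-specific entries were thus present for cardiac miRNAs such as miR-133a and miR-499, each of which was listed with its asterisk form.

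All 6 cardiomyocyte miRNAs on the list fixed in advance were listed: miR-1a, miR-133a, miR-133b, miR-208a-3p, miR-208b and miR-499. These are enriched in heart or striated muscle, and miR-208b and miR-499 lie in introns of the myosin genes Myh7 and Myh7b. Of the 9 fibroblast miRNAs, 8 were listed, among them miR-21, miR-214, miR-199a-5p and miR-199b*. The name miR-199a-3p was not matched. All 8 members of the antifibrotic list were present, namely miR-29a, miR-29b and miR-29c, which are known to target collagen mRNAs, and miR-30a to miR-30e. The 8 stress-induced miRNAs were all listed as well, including miR-210, which is induced by hypoxia, miR-34a, a target of p53, and the neighbouring pair miR-132 and miR-212-3p.

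Among the families known to act on the cell cycle, all 6 members of the miR-15 family were listed (miR-15a, miR-15b, miR-16, miR-195, miR-322 and miR-497), as were all 9 of the let-7 family, counting miR-98. Of the 12 members of the miR-17 cluster and its paralogues, 10 were listed, and miR-106a and miR-20b were not matched. The 4 members of the miR-26 and miR-101 families, which are known to target the mRNA of the histone methyltransferase EZH2, were listed as miR-26a, miR-26b, miR-101a and miR-101b.

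Markers of other cell types were also covered, including lists of markers of cells from outside the heart. The 4 endothelial entries were miR-126-3p, miR-126-5p, miR-221 and miR-222. The 3 smooth muscle entries were miR-143, miR-145 and miR-145*. All 8 leukocyte miRNAs were listed, among them miR-142-3p, the myeloid miR-223, the lymphocyte miR-150 and the inflammation-induced miR-155. Of the 4 erythroid miRNAs, 3 were listed (miR-451, miR-144 and miR-144*), and miR-486a-5p was not matched, although the table held its opposite strand as miR-486*. Of the 10 epithelial miRNAs 8 were listed, including miR-200a, miR-200b, miR-200c, miR-141 and miR-429. Of the 7 markers of other tissues 5 were listed, with the liver miRNA miR-122 and the neuronal miR-9 among them, and the neuronal miR-124-3p and the skeletal muscle miR-206-3p were not matched. A listed name gives no abundance, so these entries do not show how much of any such cell type was in the tissue.

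Over the 16 lists together, 124 of 141 different miRNAs were listed and 17 were not matched. With exact current names only, a setting chosen after the names had been seen, 14 of the 141 were found. The longest list was the imprinted Dlk1-Dio3 region, whose miRNAs are expressed from the maternal chromosome, with 31 of its 40 members listed. The 9 not matched include miR-329-3p, although the table held its opposite strand as miR-329*. All 6 members of the X-linked cluster were listed (miR-322, miR-503, miR-351, miR-542-3p, miR-450a and miR-450b-5p).

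In the gene annotation, 429 of the 440 names matched a mouse miRNA gene, 396 through the gene symbol and 33 through a synonym. They matched 327 different genes of the 1228 miRNA genes in the reference. With these matching rules, a single gene was kept for 397 names. The other 32 matched 2 or more numbered gene copies by name, and whether the mature sequence is the same in each copy was not compared. These include miR-1a (Mir1a-1 and Mir1a-2), miR-133a (Mir133a-1 and Mir133a-2), miR-29b, miR-26a, let-7a and let-7f. With 10 copies, miR-467a had the most.

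Of the 440 names, 207 matched a gene with another listed miRNA gene at most 10 kb away, in 48 clusters that held 158 genes. A name matched to several gene copies was counted where any copy lay in a cluster. The largest cluster lay on chromosome 12, in the Dlk1-Dio3 region, with 26 genes from Mir379 to Mir410 and 34 listed names. A cluster on chromosome 2 held 14 genes but 5 listed names, because 10 of its genes are copies matched to the single name miR-467a, and these copies are included in the 158 genes. A second stretch of chromosome 12 held 7 genes, Mir337, Mir540, Mir431, Mir433, Mir127, Mir434 and Mir136, and 13 listed names. Of these names, miR-127, miR-136, miR-337-5p, miR-431, miR-433 and miR-434-3p are also on the Dlk1-Dio3 list. So is miR-370, from a further chromosome 12 cluster of Mir341 and Mir370. The 10 kb limit thus divided members of this list among separate clusters. On chromosome X, the 7 genes Mir450b, Mir450-1, Mir450-2, Mir542, Mir351, Mir503 and Mir322 accounted for 10 names. The cluster of Mir17, Mir18, Mir19a, Mir20a, Mir19b-1 and Mir92-1 on chromosome 14 had 6 genes and 9 names. The miR-1a and miR-133a genes formed 2 small clusters, Mir133a-1 with Mir1a-2 on chromosome 18 and Mir1a-1 with Mir133a-2 on chromosome 2, each with 2 genes.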

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

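The 18 processing choices fixed before the data were examined were not run, because each needs the value columns that could not be matched to samples. No paired analysis was possible because the columns carry no replicate numbers and no group. The sample titles number the replicates within each group, and do not state that equal numbers mark a sham and infarcted pair. The 4 alternatives below were chosen after the names had been seen, and they concern names only. The counts of strands, the matching to genes and the clusters at 10 kb were also not part of the fixed plan. With exact current miRBase names, 14 of the 141 list members were found in place of 124. Matching genes by symbol alone gave 396 names with a gene in place of 429. Names with a listed neighbour numbered 151 at a distance of at most 1 kb and 227 at most 50 kb, against 207 at 10 kb. Whether any miRNA changed after infarction, and at what depth it was measured, was not analysed here.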

Other observations

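The 11 names with no gene in the annotation were miR-720, miR-1196, miR-1940, miR-1965, miR-3096-5p, miR-3096b-5p, miR-5097, miR-5102, miR-5105, miR-5109 and miR-5115. No explanation for their lack of a gene was tested.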
